A study of Homo sapiens with 17 samples.

How the data were processed

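RNA from sorted human lymphocytes was measured on 17 Affymetrix Human Gene 1.0 ST arrays, 4 of ILC1, 5 of ILC3, 4 of NK cells, 2 of Th1 and 2 of Th17 cells. Per the labels, RNA was purified on columns and amplified, and 2 amplification kits are named without the kit of each array. The deposited values are log2 signals that the authors made with Affymetrix Expression Console 1.2.0.20 by RMA, which corrects background, normalizes arrays by quantiles and summarises the probes of each probe set. No intensities were reprocessed here. Groups follow the sample labels, which name Th17 where the series description names Th2.

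Of 33297 probe sets, 12083 had no gene in the annotation and 1754 matched several symbols. The 19460 with 1 symbol were kept, less 24 of XIST and Y-linked genes, and the probe set with the highest mean stood for each of 768 genes that had several, which gave 18394 genes. A gene was tested when its signal lay above the 30th percentile of the array, a log2 level of 3.95 to 4.07, in at least 2 arrays, which left 15536 genes and set aside 2858. A tested gene can lie below that level in a group, and its difference from that group may then be a minimum. Arrays give no counts, so no depth can be stated, and the number of arrays limits the precision.

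One linear model with a mean per group was fitted over all 17 arrays with limma 3.58.1 in R 4.3.3, with moderated variances (12 residual degrees of freedom, 16.1 with the prior). The 8 contrasts were ILC1 less ILC3, ILC1 less NK, ILC3 less NK, the mean of ILC1 and ILC3 less the mean of Th1 and Th17 (innate less adaptive), ILC1 less Th1, ILC3 less Th17, Th1 less Th17, and the difference between ILC1 less ILC3 and Th1 less Th17 (the interaction). Adjusted p-values are limma's two-sided values by Benjamini and Hochberg over all genes of a contrast, and a gene was called below 0.05. Genes called the same way in ILC1 less Th1 and ILC3 less Th17 were compared with the number for independent lists, by Fisher's exact test. Array similarity was the mean Pearson correlation over the 1000 most variable genes, which also gave the principal components. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

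The comparisons, gene lists, rule for naming genes and alternatives were set before the data were examined. The 26 lists cover gate markers, type 1 and type 3 programs, cytotoxic machinery, NK receptors and adaptors, T cell receptor and costimulation, follicular helper program, T lineage and innate lymphoid transcription factors, tissue residency, circulation and egress, cytokine receptors, class II presentation, interferon-stimulated genes, cell cycle, glycolysis, immediate early and stress genes, ribosomal protein genes, and markers of B cells, plasma cells, monocytes and macrophages, plasmacytoid dendritic cells, epithelium, stroma and endothelium, erythrocytes and platelets, and CD8 T cells. They hold 372 memberships, of which 326 were tested, 37 were not analysed here and 9 were too dim. The 25 lists other than the gate markers were tested with limma's camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a contrast.

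Genes named in the text came from a rule with 4 parts. They are the gate markers and a fixed set of transcription factor and cytokine genes, TBX21, EOMES, GATA3, IFNG, IL22 and IL17A among them. They are the 8 genes with the highest and the 8 with the lowest differences in ILC1 less ILC3, ILC1 less NK, ILC3 less NK and innate less adaptive, 5 each way in ILC1 less Th1, ILC3 less Th17 and Th1 less Th17, and 4 each way in the interaction, among called genes whose groups do not overlap (no such condition for the interaction), skipping unnamed loci and small RNA genes. They are up to 4 called members of each list with the largest change, or 2 where none was called. They are 6 genes each way among the calls shared by the contrasts of ILC1 with Th1 and ILC3 with Th17. The rule gave 229 genes.

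For each contrast, 1 data set was simulated with 100 genes changed by a log2 of 1 and 100 others by 2. The model recovered 56% to 92% of log2 changes of 1 in the first 7 contrasts and 27% in the interaction. It recovered 88% or more of log2 changes of 2. False calls made up 1.71% to 7.69% of the calls, above 5% in ILC1 less ILC3 (5.41%), ILC1 less NK (7.18%), ILC1 less Th1 (7.69%) and ILC3 less Th17 (7.32%). Alternatives were quantile renormalization, centring on the median, no filter or the 50th percentile in place of the 30th, the median of a gene's probe sets, variance moderation with trend and robust options, array weights, only the groups compared, replicate number as a block, leaving out each array, a 2-fold minimum, and camera with an estimated correlation or fry. For array similarity every gene was used, and for the correlation of the 2 axes only genes called in ILC1 less ILC3.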

Results

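RNA levels were measured in sorted human lymphocytes on Affymetrix Human Gene 1.0 ST arrays, with 1 array per sample and 17 arrays in all. Innate lymphoid cells lack the rearranged antigen receptors of T and B cells and are grouped by the cytokines they make. Type 1 innate lymphoid cells (ILC1, n = 4) were sorted from tonsil as CD56, NKp44 and CD103 positive, and type 3 cells (ILC3, n = 5) as CD56, NKp44 and CCR6 positive. Helper T cells of the same tissue were sorted as CD4 and CXCR3 positive (Th1, n = 2) or as CD4 and CCR6 positive (Th17, n = 2). Natural killer cells (NK, n = 4) were sorted from blood by low CD56 without NKp44. Every NK array therefore differs from the other 13 in tissue as well as in cell type. The arrays give no read depth, and their number limits the precision. Nothing in the labels says that replicates came from separate donors, so p-values measure only the spread between these samples, which may be technical. The study set innate against adaptive lymphoid cells and type 1 against type 3 cells within each.

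Over the most variable genes the 5 populations lay apart on average, and ILC1 arrays resembled ILC3 and NK arrays about equally. Over the 1000 genes with the highest variance, the mean Pearson correlation across genes was 0.692 between ILC1 and ILC3 arrays, 0.701 between ILC1 and NK arrays and 0.453 between ILC3 and NK arrays. Th1 and Th17 arrays correlated at 0.809, close to the 0.876 to 0.912 within groups, and helper T cells correlated with the innate groups at 0.354 to 0.479. The first principal component held 36.4% of the variance and the second 33.3%. Single pairs ran from 0.594 to 0.840 for ILC1 with ILC3 and from 0.620 to 0.774 for ILC1 with NK. ILC1 replicate 1 lay toward ILC3 on the second component, at -15.0 against -3.54 to -0.468 in the other ILC1 arrays. The ILC3 arrays lay at -34.1 to -29.0. Genes are not independent replicates, and no test was made here. Correlations within groups exceeded those between groups by 0.375 on average, and by 0.0534 over every gene tested. Over every gene, single pairs of arrays overlapped: the highest Th1 and Th17 pair had 0.960 against 0.955 for the 2 Th1 arrays, and the highest ILC1 and ILC3 pair 0.957 against 0.947 for the lowest ILC1 pair.

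**Figure D1:**
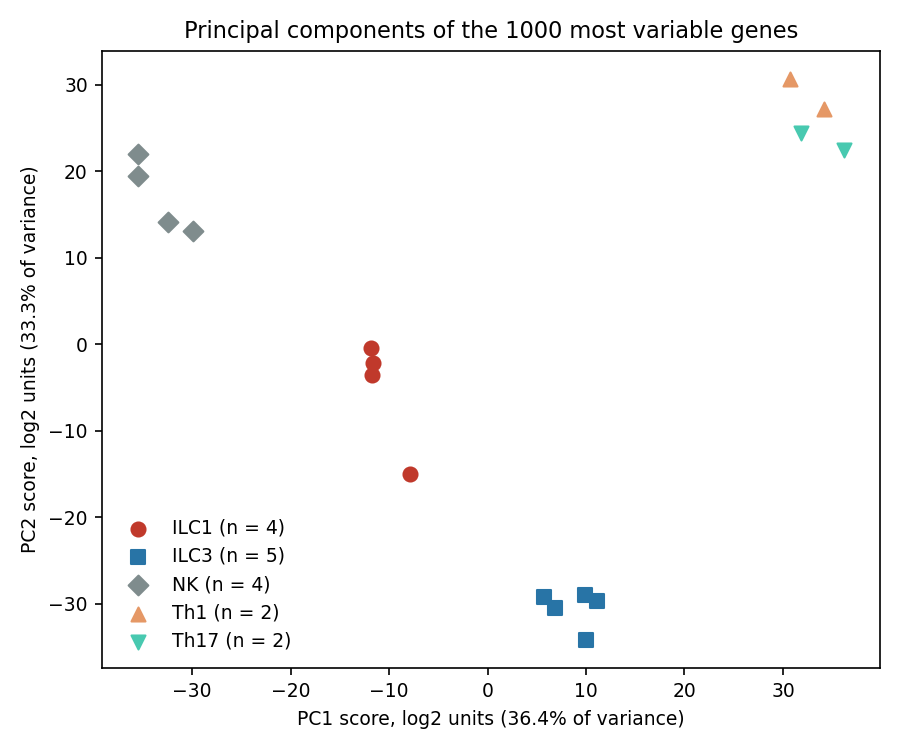
Scores of the 17 arrays on the first 2 principal components (PC1 and PC2, log2 units) of the 1000 most variable genes; each point is an array, with colour and shape giving the group. NK arrays lie at the left (PC1 from -35.5 to -29.9), helper T cells at the right (30.7 to 36.2), and the innate cells of tonsil between them.

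The genes behind the sort gates followed the labels, and where they were sort criteria of the groups compared they are no finding. ITGAE, which encodes CD103, averaged 8.85 ± 0.42 on the log2 scale (SD, n = 4) in ILC1 and was at most 5.41 on each other array. NCAM1, which encodes CD56, was higher in tonsil innate cells than in helper T cells by 5.01 ± 0.19 on the log2 scale (SE), and NCR2, which encodes NKp44, by 3.83 ± 0.26. CD4 was lower in the innate cells (log2 difference -5.68 ± 0.27). CCR6 was lower in Th1 than in Th17 (-3.15 ± 0.46, adjusted p = 0.00116). It was also lower in ILC1 than in ILC3 (-1.34 ± 0.31, adjusted p = 0.0129), a call lost without ILC1 replicate 4 (adjusted p = 0.0540) and when these 2 groups were fitted alone (0.0668). CXCR3, a gate of Th1 alone, was higher in ILC1 than in ILC3 (2.46 ± 0.28, adjusted p = 4.52e-05), which the sort does not fix. It differed little between ILC1 and Th1 (0.07 ± 0.37, adjusted p = 0.957).

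ILC1 had higher levels of interferon gamma, granzyme and several killer receptor transcripts than ILC3, and ILC3 had higher levels of IL22 and of the receptors for interleukin-23, interleukin-1 and stem cell factor. IFNG, the signature cytokine of type 1 responses, averaged 9.10 ± 0.73 (log2, SD, n = 4) in ILC1 and 4.70 ± 0.73 (n = 5) in ILC3, a difference of 4.39 ± 0.48 (SE, adjusted p = 2.31e-05). IL22, which acts on epithelial barriers, averaged 4.93 ± 1.63 in ILC1 and 9.60 ± 0.64 in ILC3 (difference -4.67 ± 0.72, adjusted p = 0.000617). Every ILC1 array lay above every ILC3 array for IFNG and below for IL22. IL17A was low in both groups and did not differ (-0.07 ± 0.23, adjusted p = 0.934). The transcription factors of type 1 cells were higher in ILC1, TBX21 (T-bet) by 1.10 ± 0.19 and EOMES by 1.79 ± 0.21.

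Of 18 type 1 program genes, 11 were higher in ILC1, 1 was lower and 6 were not called. Adjusted over the list alone, 12 were higher and 2 lower. Besides IFNG, the examples were IKZF3 (4.09) and the chemokines CCL4 (4.04) and CCL3 (2.93). The exception was IL18R1, a subunit of the interleukin-18 receptor, which was lower by 1.40 (log2 difference -1.40). Of 21 type 3 program genes, 14 were lower in ILC1, 0 higher and 7 not called, and 15 were lower adjusted over the list alone. They included IL23R (-4.36), IL1R1 (-4.06) and IL26 (-3.53). With limma's camera test the type 1 list stood above other genes (adjusted p = 6.98e-11) and the type 3 list below (1.29e-17), each with adjusted p = 0.0109 with an estimated correlation.

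Killing genes were also higher in ILC1. Of 16 cytotoxic genes, 10 were higher in ILC1, 0 lower and 6 not called (12 higher adjusted over the list alone), among them GZMA (4.25), GZMK (4.03), GZMB (3.43) and CST7 (2.99). Of 17 NK receptor and adaptor genes, 8 were higher, 1 lower and 8 not called, and adjusted over the list alone 9 were higher and 1 lower. CD160 (4.69) and KLRF1 (4.16), both activating receptors, and FCGR3A (2.84), the Fc receptor CD16, led this list. Both lists passed camera (adjusted p = 2.21e-17 and 2.75e-09), with adjusted p = 0.0109 with an estimated correlation for each. Of 13 tissue residency genes, 4 were higher and 9 were not called (5 higher and 1 lower adjusted over the list alone), with ZNF683 at 2.25, NR4A2 at 2.05 and TNFRSF9 at 1.52. That list gave adjusted p = 0.000251, and adjusted p = 0.0170 with an estimated correlation.

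ILC3 held other receptors at higher levels. ICOS (-2.48), a costimulatory receptor, THEMIS (-2.55), a T cell signalling protein, and MYB (-1.70), a transcription factor of progenitor cells, were lower in ILC1, as were the homing receptors CCR7 (-1.28) and CXCR5 (-1.54). TIGIT (3.06), SH2D1A (3.49) and CD247 (2.35) were higher in ILC1. SH2D1A encodes the signalling adaptor SAP and CD247 the zeta chain of the T cell receptor, which NK cells also use. The T cell receptor list went both ways, with 4 of 18 members higher, 2 lower and 12 not called (7 and 3 adjusted over the list alone), and did not pass (adjusted p = 0.378). Outside the lists, ENPP1 (-4.19), SPINK2 (-3.91), ELAPOR1 (-3.75), IRAK3 (-3.69) and GNAI1 (-3.56) were lower in ILC1, and PYHIN1 was higher (4.09), each with the groups apart on every array.

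Cell cycle transcripts were somewhat higher in ILC1. Of 16 genes, 5 were higher, 0 lower and 11 not called, with TYMS at 2.16 and BUB1 at 1.96, and 10 were higher adjusted over the list alone. Camera gave adjusted p = 6.51e-07, and adjusted p = 0.149 with an estimated correlation. The immediate early list moved the same way, with 2 of 18 members higher in ILC1 (3 adjusted over the list alone) and adjusted p = 0.00201, but adjusted p = 0.492 with an estimated correlation and 0.0682 without ILC1 replicate 4. Of 12 innate transcription factor genes, 5 were higher in ILC1 and 2 lower (6 and 2 adjusted over the list alone), led by ZEB2 (2.44). Its adjusted p was 0.0176, and adjusted p = 0.111 with an estimated correlation. The call was also lost without ILC1 replicate 4 (0.0640) or NK replicate 1 (0.0551). MS4A1, the B cell marker CD20, was higher in ILC1 (2.24) while BANK1, another B cell gene, was lower (-1.71), and the other 12 of 14 B cell markers were not called.

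In limma's test over 15536 genes, 906 differed between ILC1 and ILC3, 413 higher in ILC1 and 493 lower. For 769 of them the groups did not overlap, with unnamed loci and small RNA genes left out of this number. Chance gives such separation for 1.59% of unselected genes. That share does not apply to genes already called on the same arrays, since the call favours separation. ILC1 replicate 1 carried more type 3 transcripts than its fellows, with IL22 at 7.21, IL23R at 8.84 and KIT at 10.16. Without it the count of called genes was 1048.

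**Figure D2:**
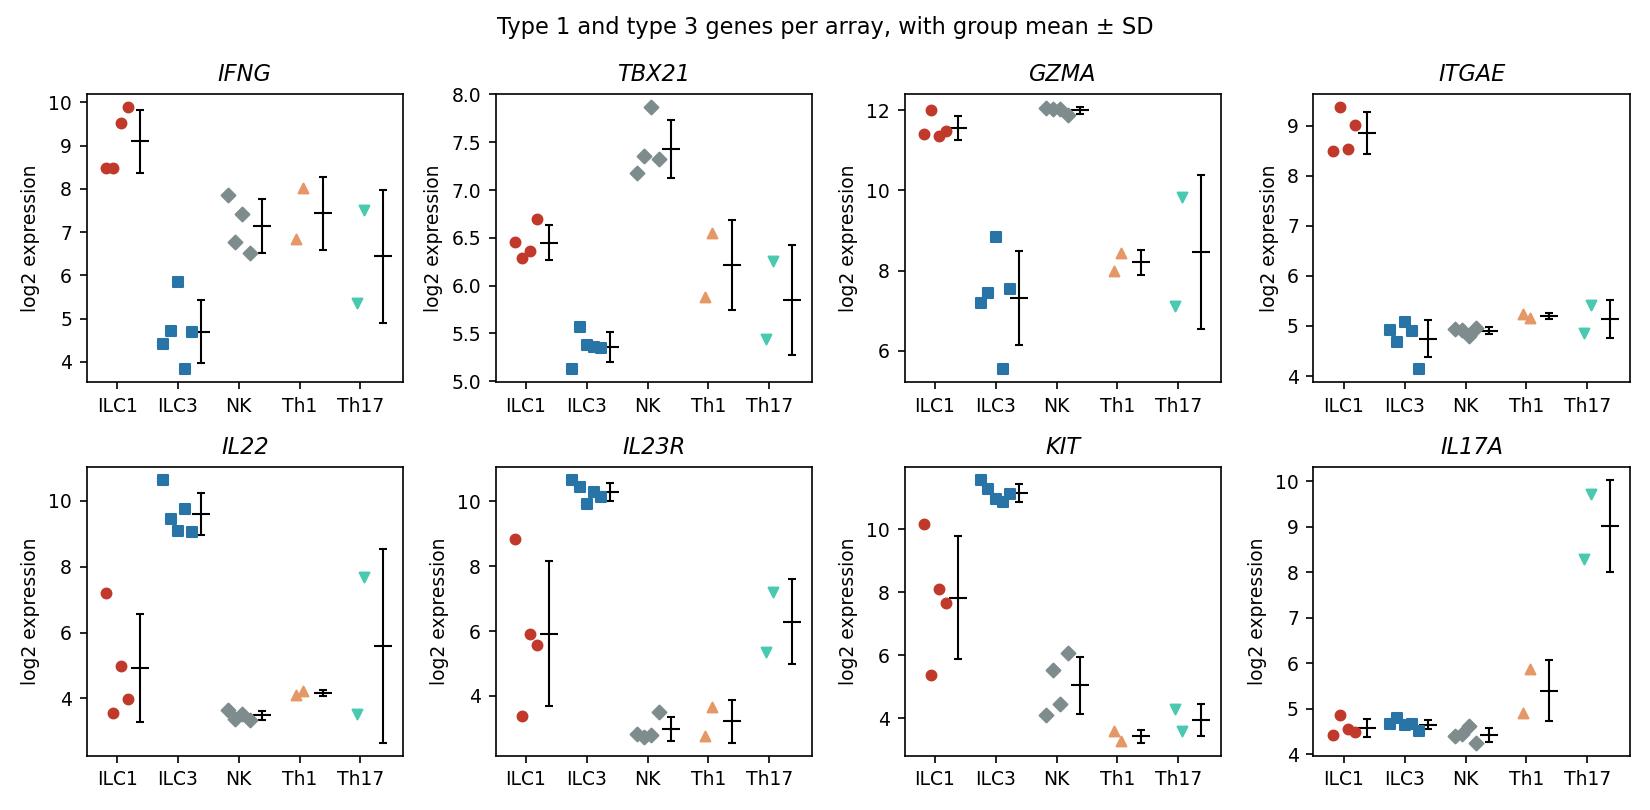
Log2 expression of 8 genes per array in each of the 5 groups, with group mean and SD beside the points. ILC1 arrays have the highest IFNG and ITGAE, ILC3 arrays the highest IL22, IL23R and KIT, and Th17 arrays the highest IL17A, whose mean is 9.02 there.

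Compared with blood NK cells, ILC1 of tonsil had lower levels of transcripts typical of circulating killer cells and higher levels of those typical of resident cells. CX3CR1, the fractalkine receptor of patrolling cells, was lower in ILC1 by 6.52 (log2 difference -6.52 ± 0.32, adjusted p = 3.76e-09), and S1PR1, the receptor for exit from tissue, by 4.25 (-4.25 ± 0.17). CX3CR1 averaged 3.59 in ILC1, below the filter level of 3.95 to 4.07, so its difference may be a minimum. ENTPD1, which encodes CD39 (3.60 ± 0.32), and CRTAM (3.25) were higher. ITGAE was higher too (3.95 ± 0.21), as the CD103 gate of ILC1 fixes. TBX21 was lower in ILC1 (-0.98 ± 0.20, adjusted p = 0.00438), while EOMES was not called (-0.49 ± 0.22, adjusted p = 0.217). Blood and tonsil cannot be told apart from the cell types in this comparison or in that of ILC3 with NK cells.

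Of 13 circulation genes, 10 were lower in ILC1, 0 higher and 3 not called, with KLF3 at -3.87 and CXCR2 at -3.13, and 11 were lower adjusted over the list alone. Of 13 tissue residency genes, 7 were higher, 1 lower and 5 not called, the same numbers as adjusted over the list alone, with CXCR6 at 2.73 and RGS1 at 2.54. The circulation list gave adjusted p = 2.94e-20 and the residency list 1.31e-07, and these were 0.000562 and 0.00312 as adjusted p with an estimated correlation.

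Part of the killing machinery was lower in ILC1. Of 16 cytotoxic genes, 6 were lower, 0 higher and 10 not called, both over all genes and adjusted over the list alone. FGFBP2 (-5.12), GZMH (-3.21) and PRF1, which encodes perforin (-1.60), led them. Camera gave adjusted p = 0.000297, and adjusted p = 0.230 with an estimated correlation. FCGR3A was lower (-3.10), and the NK receptor list as a whole was not called (6 of 17 lower and 1 higher, 7 and 1 adjusted over the list alone, adjusted p = 0.128). PRDM1 was lower (-2.67) and the chemokine XCL1 higher (1.60), and the type 1 list went both ways with 3 of 18 members higher and 4 lower (5 and 4 adjusted over the list alone, adjusted p = 0.842).

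ILC1 also held more of some type 3 transcripts than NK cells. Of 21 genes, 7 were higher, 1 lower and 13 not called (10 and 2 adjusted over the list alone), with AHR, the aryl hydrocarbon receptor, at 2.88. Camera gave adjusted p = 9.78e-06, and adjusted p = 0.220 with an estimated correlation. The list mean was 7.27 in ILC1 replicate 1, 5.63 to 6.33 in the other ILC1 arrays and at most 5.59 in NK arrays. The median difference was 0.95, and 0.47 without ILC1 replicate 1 (adjusted p = 0.000525). The T cell genes TRAT1 (3.72), ICOS (2.59), THEMIS (1.64) and CTLA4 (1.35) were higher in ILC1, with 5 of 18 members of the T cell receptor list higher and 2 lower (6 and 3 adjusted over the list alone, adjusted p = 0.128). GPR82 (4.04), ZNF667-AS1 (3.86) and RAB3GAP1 (3.56) were among the genes with the highest differences outside the lists. AKR1C3 (-4.21), GPR141 (-4.15), AK5 (-4.08) and PRSS23 (-3.96) were among the lowest.

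Early response and other lists differed alongside. Of 18 immediate early and stress genes, 11 were higher in ILC1, 0 lower and 7 not called, with EGR1 at 3.92, FOSB at 2.80, FOS at 1.88 and JUN at 1.78, and 14 were higher adjusted over the list alone (adjusted p = 5.96e-19, and adjusted p = 0.0205 with an estimated correlation). Monocyte markers were lower in ILC1, 4 of 11 over all genes and 6 adjusted over the list alone, led by LYZ, which encodes lysozyme (-5.06). Class II presentation genes were lower too, 5 of 8 and 7 adjusted over the list alone, with HLA-DQA1 at -2.67, HLA-DPA1 at -2.09 and HLA-DPB1 at -2.08. The monocyte list had adjusted p = 9.46e-05, and adjusted p = 0.194 with an estimated correlation. The class II list had adjusted p = 9.78e-06, and adjusted p = 0.125 with an estimated correlation. The mean of the monocyte list was highest in NK replicates 3 and 4, at 6.22 and 6.01, and lay at 5.23 and 5.28 in NK replicates 1 and 2. It was 4.31 to 4.59 in ILC3 and 4.45 to 5.03 in helper T arrays, so the NK arrays stood apart rather than ILC1. The class II mean was 6.68, 7.47, 7.60 and 7.87 in NK replicates 1 to 4. Whether other cells in the NK preparations carried these transcripts was not tested.

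In all, 1379 genes differed between ILC1 and NK cells, 486 higher in ILC1 and 893 lower. Of these, 1193 were free of overlap between the groups, with unnamed loci and small RNA genes left out. The chance share of 2.86% holds for unselected genes and not for called ones. Without NK replicates 3 and 4 the count of called genes was 733, and without replicates 1 and 2 it was 763, both chosen after seeing the data.

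More genes were called between ILC3 and NK cells than between any other 2 groups compared. The simulation recovered 82% of log2 changes of 1 here, 59% in ILC3 less Th17 and 57% in ILC1 less Th1. The ranking therefore also reflects the number of arrays. Over the 1000 most variable genes ILC3 correlated at 0.453 with NK and at 0.425 with Th17 arrays. IL23R was higher in ILC3 by 7.32 ± 0.71 (adjusted p = 1.80e-06), and IL1R1 by 6.36 ± 0.51, KIT by 6.12 ± 0.64 and IL22 by 6.12 ± 0.72. IL7R, the receptor for interleukin-7, was higher by 5.53 ± 0.83. In NK cells IL23R (mean 2.97) and IL22 (3.48) lay below the filter level of 3.95 to 4.07, so their differences may be minimums. IFNG was lower in ILC3 (-2.44 ± 0.48, adjusted p = 0.00157), as were TBX21 (-2.08 ± 0.19) and EOMES (-2.28 ± 0.21). PLEK (-5.52 ± 0.16) and TGFBR3 (-5.21 ± 0.22) were lower with small errors.

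Of 21 type 3 genes, 15 were higher in ILC3, 0 lower and 6 not called, also with TNFSF4, the OX40 ligand, at 5.58, and 15 were higher and 1 lower adjusted over the list alone. Of 16 cytotoxic genes, 15 were lower and 1 was not called, with GZMH at -5.15, GZMA at -4.69 and PRF1 at -4.57, and 16 were lower adjusted over the list alone. Of 17 NK receptor genes, 12 were lower, 1 higher and 4 not called (13 and 1 adjusted over the list alone), with FCGR3A at -5.94, KLRF1 at -4.71 and CD160 at -3.98. Of 13 circulation genes, 11 were lower, 1 higher and 1 not called (12 and 1 adjusted over the list alone), with CX3CR1 at -6.48. These 4 lists passed camera (adjusted p from 1.24e-15 to 1.21e-08) and had adjusted p from 0.00281 to 0.0172 with an estimated correlation.

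Of 18 type 1 genes, 12 were lower in ILC3, 3 higher and 3 not called (12 and 4 adjusted over the list alone), with CCL4 at -4.68, PRDM1 at -4.55 and CCL3 at -3.40. That list gave adjusted p = 5.79e-05, and adjusted p = 0.128 with an estimated correlation. Of 16 cell cycle genes, 7 were lower, 0 higher and 9 not called (9 lower adjusted over the list alone), with RRM2 at -2.12, MKI67 at -1.88 and TYMS at -1.85. It gave adjusted p = 0.000263, and adjusted p = 0.279 with an estimated correlation. Residency genes went both ways, with 6 of 13 higher, among them ENTPD1 (3.27), CRTAM (2.85) and CXCR6 (2.52), and 4 lower (6 and 5 adjusted over the list alone, adjusted p = 0.151).

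ICOS (5.07) and THEMIS (4.19) were higher in ILC3, while CD247 was lower (-2.42), and the T cell receptor list split into 5 higher, 5 lower and 8 not called (6 and 7 adjusted over the list alone, adjusted p = 0.795). ZEB2 (-4.53) and AHR (4.43) led the innate transcription factors in opposite directions. Immediate early genes were higher in ILC3, 9 of 18 and 10 with 1 lower adjusted over the list alone, with EGR1 at 3.65 and FOSB at 2.84. The list gave adjusted p = 1.64e-07, and adjusted p = 0.168 with an estimated correlation. Monocyte markers were lower, 6 of 11 and 8 adjusted over the list alone, with LYZ at -5.97 and S100A8 at -2.27, at adjusted p = 0.000708 and adjusted p = 0.238 with an estimated correlation. Class II genes were lower, 3 of 8 and 4 adjusted over the list alone, at adjusted p = 0.00887 and adjusted p = 0.279 with an estimated correlation. As in the comparison with ILC1, other cells in the NK preparations were not tested as a source of the monocyte and class II transcripts.

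In all, 2837 genes differed between ILC3 and NK cells, 1152 higher in ILC3 and 1685 lower. Of these, 2277 had no overlap between the groups, with unnamed loci and small RNA genes left out. The chance share of 1.59% holds for unselected genes and not for called ones. Without NK replicates 3 and 4 the count of called genes was 1830, and without replicates 1 and 2 it was 1819, both chosen after seeing the data.

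Within tonsil, innate cells were set against helper T cells by the mean of ILC1 and ILC3 less the mean of Th1 and Th17. The lymphotactins XCL1 (7.53 ± 0.25, adjusted p = 2.84e-12) and XCL2 (6.64 ± 0.27) were the genes with the highest innate excess, followed by the signalling adaptor SH2D1B (6.33 ± 0.15), the inhibitory receptor KLRC1 (6.32 ± 0.52) and ATP8B4 (6.21 ± 0.18). The costimulatory and inhibitory receptors CTLA4 (-5.67 ± 0.24) and CD28 (-5.66 ± 0.24), the receptor chain CD3G (-5.50 ± 0.65) and the B cell attractant CXCL13 (-4.99 ± 0.20) were lower in innate cells. TBX21 (-0.13 ± 0.17, adjusted p = 0.712), GATA3 (-0.10 ± 0.13, adjusted p = 0.712) and IFNG (-0.04 ± 0.43, adjusted p = 0.977) were not called between the 2 classes. IL17A was lower in innate cells (-2.59 ± 0.21, adjusted p = 1.88e-07).

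Of 17 NK receptor and adaptor genes, 14 were higher in innate cells, 0 lower and 3 not called (15 higher adjusted over the list alone), with FCER1G at 5.62 and KLRF1 at 4.56. Of 18 T cell receptor genes, 14 were lower and 4 not called (17 lower adjusted over the list alone), with CD5 at -4.75. Of 13 follicular helper genes, 11 were lower and 2 not called (12 lower adjusted over the list alone), with IL21, the helper cytokine for B cells, at -4.74, BTLA at -4.21 and CXCR5 at -3.50. Camera gave adjusted p of 4.70e-27, 8.19e-23 and 9.16e-19, and adjusted p of 7.43e-05, 1.05e-05 and 2.72e-05 with an estimated correlation.

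Transcription factors divided likewise. Of 12 innate lymphoid factors, 7 were higher in innate cells, 1 lower and 4 not called, the same numbers as adjusted over the list alone, with NFIL3 at 3.20, ZNF683 at 2.47, IKZF2 at 1.81 and ZBTB16 at 1.79. Of 11 T lineage factors, 5 were lower and 6 not called (7 lower adjusted over the list alone), with LEF1 at -2.97, FOXP3 at -1.88 and BCL11B at -1.28. These lists gave adjusted p = 9.54e-06 and 7.41e-05, and adjusted p of 0.00535 and 0.0135 with an estimated correlation.

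Effector programs were partly innate. Of 18 type 1 genes, 11 were higher in innate cells, 2 lower and 5 not called, as also adjusted over the list alone, with IL18RAP at 4.06 and CCL5 at 3.94 (adjusted p = 2.72e-08, and adjusted p = 0.0181 with an estimated correlation). Of 16 cytotoxic genes, 7 were higher, 1 lower and 8 not called (9 and 2 adjusted over the list alone), with CTSW at 5.89, GNLY at 5.64 and NKG7 at 3.38. That list gave adjusted p = 2.51e-06, and adjusted p = 0.0777 with an estimated correlation. Type 3 genes went both ways, with 8 of 21 higher, among them KIT (5.80) and TNFSF4 (3.48), and 5 lower, among them MAF (-3.57). That list was not called (9 and 5 adjusted over the list alone, adjusted p = 0.348). Among cytokine receptors IL6R was lower in innate cells (-3.29), and IL18R1 (1.86) and IL2RB (1.48) were higher, with 4 of 16 higher and 4 lower, as also adjusted over the list alone (adjusted p = 0.348).

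Weaker lists were lost with an estimated correlation. Residency genes, 4 of 13 higher and 2 lower (5 and 2 adjusted over the list alone), gave adjusted p = 0.0362, and adjusted p = 0.130 with an estimated correlation. Circulation genes, 5 of 13 lower and 1 higher, as also adjusted over the list alone, gave adjusted p = 0.0498, and adjusted p = 0.352 with an estimated correlation, led by CCR7 at -3.44. Ribosomal protein genes, 4 of 24 lower and 7 adjusted over the list alone, gave adjusted p = 0.00382, and adjusted p = 0.453 with an estimated correlation. Class II genes, 4 of 8 lower and 5 adjusted over the list alone, gave adjusted p = 0.0494, and adjusted p = 0.453 with an estimated correlation. The residency call was also lost without ILC1 replicate 4 or Th1 replicate 2 (adjusted p up to 0.0596). The class II call was lost without ILC1 replicate 2 or 4, ILC3 replicate 1 or 5, Th1 replicate 2 or Th17 replicate 1 (up to 0.143). The circulation call was lost without any of these 6 arrays, ILC1 replicate 1 or NK replicate 1 or 2 (up to 0.0916). B cell markers were lower in innate cells, 13 of 14 both over all genes and adjusted over the list alone, with CD79A at -2.51, CD22 at -2.44 and CR2 at -2.35 (adjusted p = 1.17e-17, and adjusted p = 6.94e-05 with an estimated correlation). Both Th17 arrays held these markers at a mean of 7.65 ± 0.05 (SD, n = 2), and both Th1 arrays at 4.71 ± 0.05.

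In all, 2112 genes differed between innate and helper T cells, 994 higher in innate cells and 1118 lower. For 887 of them all innate arrays lay above or below all helper T arrays, with unnamed loci and small RNA genes left out. The chance share of 0.280% holds for unselected genes and not for called ones. Without the Th17 arrays the contrast gave 1473 genes, a check chosen after the B cell markers were seen.

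**Figure D3:**
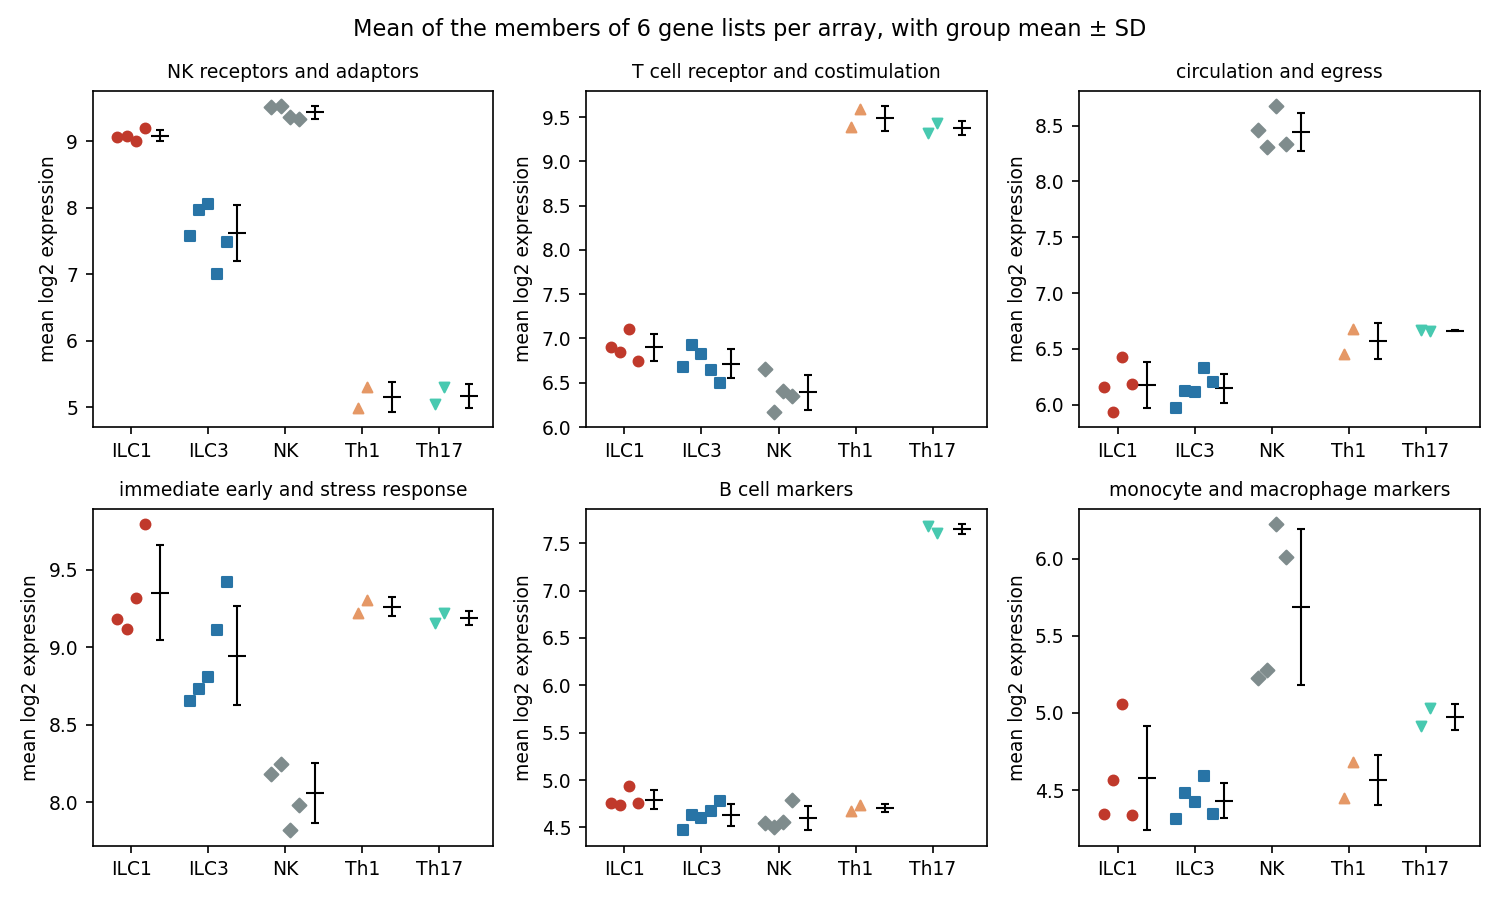
Mean log2 expression of the measured members of 6 fixed gene lists per array, with group mean and SD beside the points. NK receptor genes are lowest and T cell receptor genes highest in helper T cells, circulation genes are highest in NK cells and immediate early genes lowest there, and B cell markers are high in both Th17 arrays.

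ILC1 were also set against Th1 cells, their adaptive counterpart. XCL1 (7.34 ± 0.36), KLRC1 (6.64 ± 0.75), KLRF1 (6.46 ± 0.59) and GNLY, which encodes granulysin (6.37 ± 0.44), were higher in ILC1. CD28 (-5.94 ± 0.35), CXCL13 (-5.68 ± 0.28), CTLA4 (-5.53 ± 0.34) and TNIP3 (-5.24 ± 0.38) were lower. In ILC1 the means of CXCL13 (3.08) and TNIP3 (3.84) lay below the filter level of 3.95 to 4.07, and CD28 (3.99) lay at it. The differences of CXCL13, TNIP3 and CD28 may therefore be minimums. EOMES was higher in ILC1 (1.57 ± 0.27, adjusted p = 0.00112), while TBX21 (0.23 ± 0.24, adjusted p = 0.711) and IFNG (1.66 ± 0.62, adjusted p = 0.143) were not called.

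Of 17 NK receptor genes, 14 were higher in ILC1 over all genes and adjusted over the list alone, and 3 were not called, with CD160 at 6.28. Of 18 type 1 genes, 9 were higher, 1 lower and 8 not called (13 and 2 adjusted over the list alone), with XCL2 at 6.49 and IL18RAP at 5.08, and of 16 cytotoxic genes 8 were higher and 8 not called (9 and 1 lower adjusted over the list alone), with CTSW at 6.28 and NKG7 at 4.40. Of 12 innate transcription factors, 7 were higher and 5 not called (7 and 2 lower adjusted over the list alone), with NFIL3 at 3.58, ZNF683 at 3.50 and ID2 at 2.49. Of 13 residency genes, 5 were higher, 1 lower and 7 not called (6 and 1 adjusted over the list alone), with CRTAM at 5.65. Of 18 T cell receptor genes, 13 were lower, 1 higher and 4 not called (14 and 1 adjusted over the list alone), and of 13 follicular helper genes 9 were lower and 4 not called (11 adjusted over the list alone), with IL21 at -5.18. Of 11 T lineage factors, 2 were lower, MYB (-2.07) and FOXP3 (-1.85), and 5 adjusted over the list alone. These 8 lists passed camera, at adjusted p of 0.000244 or less, and had adjusted p of at most 0.0133 with an estimated correlation. Type 3 genes (1 higher, 1 lower, 5 and 6 adjusted over the list alone, MAF at -4.20) and circulation genes (1 higher, 3 lower, 1 and 5 adjusted over the list alone, CCR7 at -3.80) were not called as lists. The 2 lists had adjusted p = 0.944 and 0.352.

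In all, 1029 genes differed, 505 higher in ILC1 and 524 lower. Th1 had 2 arrays, and the count was 668 without Th1 replicate 1, when the spread of the lone Th1 array was taken from the other groups. It was 604 when the 2 groups were fitted alone.

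ILC3 were set against Th17 cells in the same way. XCL1 (7.73 ± 0.35), KIT (7.22 ± 0.80), ENPP1 (6.96 ± 0.86), XCL2 (6.79 ± 0.38) and SH2D1B (6.59 ± 0.21) were higher in ILC3, and CD3G (-6.03 ± 0.91), CTLA4 (-5.80 ± 0.33), CD28 (-5.38 ± 0.34) and MS4A1 (-5.65 ± 0.43) were lower. The type 3 cytokines divided: IL17A was lower in ILC3 (-4.36 ± 0.29, adjusted p = 3.01e-08) and IL22 higher (4.0 ± 0.90, adjusted p = 0.00838). The IL22 difference rested on the Th17 arrays, which held 3.52 and 7.68, and it was 1.92 without Th17 replicate 1 (adjusted p = 0.303) and 6.08 without Th17 replicate 2.

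Of 17 NK receptor genes, 10 were higher in ILC3 and 7 not called (12 adjusted over the list alone), with FCER1G at 5.77 and TYROBP at 4.24. Of 18 T cell receptor genes, 12 were lower and 6 not called (14 adjusted over the list alone), with CD3D at -5.17. Of 13 follicular helper genes, 10 were lower and 3 not called (10 and 1 higher adjusted over the list alone), with IL21 at -4.30, CXCL13 at -4.30 and BTLA at -3.77. Of 12 innate transcription factors, 5 were higher and 1 lower (7 and 2 adjusted over the list alone), with NFIL3 at 2.81, IKZF2 at 1.83 and ZEB2 at -2.28. These 4 lists passed camera (adjusted p from 2.33e-22 to 0.00124) and had adjusted p of at most 0.0341 with an estimated correlation. T lineage factors, 3 of 11 lower and 4 adjusted over the list alone, gave adjusted p = 0.0164, and adjusted p = 0.130 with an estimated correlation, with LEF1 at -4.03, FOXP3 at -1.91 and BCL11B at -1.91.

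Type 1 genes, 7 of 18 higher and 2 lower (8 and 4 adjusted over the list alone), gave adjusted p = 0.000591, and adjusted p = 0.142 with an estimated correlation, with CCL5 at 4.33 and PRDM1 at -4.48. Cytotoxic genes, 4 of 16 higher and 2 lower (5 and 3 adjusted over the list alone), gave adjusted p = 0.0361, and adjusted p = 0.544 with an estimated correlation, with CTSW at 5.51 and GNLY at 4.91. Type 3 genes, 8 of 21 higher and 4 lower (10 and 5 adjusted over the list alone), gave adjusted p = 0.0480, and adjusted p = 0.568 with an estimated correlation, with TNFSF4 at 4.58. Circulation genes, 4 of 13 lower and 1 higher (5 and 1 adjusted over the list alone), gave adjusted p = 0.0113, and adjusted p = 0.189 with an estimated correlation, with CCR7 at -3.08 and S1PR1 at -1.58. The cytotoxic call was also lost without ILC3 replicate 3 (adjusted p = 0.0901) or Th17 replicate 1 (0.165). The type 3 call was lost without any 1 of 8 arrays (adjusted p up to 0.30, without Th17 replicate 1) and with fry (0.933).

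B cell markers were lower in ILC3 for 14 of 14 genes over all genes and adjusted over the list alone, with CD22 at -5.11, CR2 at -4.58 and CD79A at -3.85 (adjusted p = 1.54e-32, and adjusted p = 5.85e-06 with an estimated correlation). Class II genes were lower with them, 6 of 8 over all genes and adjusted over the list alone, with HLA-DPB1 at -2.74 and CD86 at -2.01 (adjusted p = 3.02e-05, and adjusted p = 0.107 with an estimated correlation). Ribosomal protein genes had no member called over all genes or adjusted over the list alone, while the list gave adjusted p = 0.00135, and adjusted p = 0.407 with an estimated correlation. That call was lost without Th17 replicate 1 (adjusted p = 0.0605).

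In all, 1295 genes differed between ILC3 and Th17 cells, 647 higher in ILC3 and 648 lower. The count was 718 without Th17 replicate 1 and 750 without Th17 replicate 2, and 1244 when genes that follow the B cell markers were left out, a check chosen after the data were seen.

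The comparisons of ILC1 with Th1 and of ILC3 with Th17 share no array. They had 239 genes in common that were higher in the innate cells and 249 that were lower, against 21.0 and 21.9 for independent lists of the same lengths, and 15 genes were called in opposite directions against 42.9. Fisher's exact test across genes gave p = 9.97e-205 and 1.35e-214, as a description, since genes are not independent. Both contrasts also take the variance of a gene from 1 fit, so genes of small spread are called more readily in both. The numbers for independent lists are therefore no chance level. The shared genes with the highest smaller difference were XCL1, XCL2, SH2D1B, ATP8B4, KLRC1 and CRTAM among those higher, and CD4, CTLA4, CD28, CD3G, CD5 and ADTRP, a gene with an innate difference of -4.62, among those lower. The total of 488 was 319 without Th17 replicate 1.

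Between Th1 and Th17 cells the B cell, class II and follicular helper lists differed, as did IL17A, IL17F and GZMK, while the T cell receptor list was not called. IL17A was lower in Th1 (-3.62 ± 0.34, adjusted p = 1.50e-05) and IL17F too (-2.41, adjusted p = 2.50e-06), the cytokines that name Th17 cells. The IL17A call was lost when the 2 groups were fitted alone (adjusted p = 0.119). IL22 was not called (-1.44 ± 1.07, adjusted p = 0.999), nor was IFNG (1.00 ± 0.71, adjusted p = 0.999). PVALB, which encodes a calcium-binding protein, was higher in Th1 (3.64 ± 0.21, adjusted p = 7.65e-08). CXCR3, a sort marker, was higher (2.52 ± 0.42, adjusted p = 0.00412), a call lost without Th1 replicate 2 or Th17 replicate 1 (adjusted p up to 0.108). GZMK (6.13 ± 1.30, adjusted p = 0.0293) was the gene with the highest Th1 excess, and leaving out any 1 of the 4 helper T arrays ended its call (adjusted p up to 0.225).

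B cell markers were lower in Th1 for 12 of 14 genes, and 13 adjusted over the list alone, with CD22 at -5.38, MS4A1 at -5.36, BANK1 at -5.08 and CR2 at -4.42, and CD24, which is also a B cell gene, was at -4.42. The list gave adjusted p = 8.91e-63, and adjusted p = 1.65e-07 with an estimated correlation. Class II genes were lower with them, 4 of 8 and 7 adjusted over the list alone, with HLA-DMB at -3.94 and HLA-DPA1 at -2.84 (adjusted p = 5.31e-18, and adjusted p = 0.00332 with an estimated correlation). The follicular helper list was higher in Th1, 2 of 13 and 3 adjusted over the list alone, at adjusted p = 1.10e-06 and adjusted p = 0.00332 with an estimated correlation. Those 2 genes were TOX2 and CXCL13 (1.48). TOX2 lost its call without any 1 of the 4 helper T arrays (adjusted p up to 0.203). CXCL13 lost its call without any 1 of 14 arrays, at 0.79 and adjusted p = 0.438 without Th1 replicate 2.

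Type 3 genes were lower in Th1, 3 of 21 and 7 adjusted over the list alone, at adjusted p = 5.28e-08 and adjusted p = 0.139 with an estimated correlation. Cytotoxic genes (1 of 16 higher, also adjusted over the list alone), cell cycle genes (1 of 16 higher, 2 adjusted over the list alone) and ribosomal protein genes (0 of 24, also adjusted over the list alone) gave adjusted p = 0.0333, 0.00327 and 0.00327. Each of these had adjusted p = 0.616 with an estimated correlation, and each call was lost without Th1 replicate 2 (adjusted p up to 0.891) or Th17 replicate 1 (up to 0.488). Type 1 genes (1 of 18 higher and 1 lower, also adjusted over the list alone, adjusted p = 0.184), T cell receptor genes (0 of 18 called, also adjusted over the list alone, adjusted p = 0.318) and NK receptor genes (0 of 17, likewise, adjusted p = 0.757) were not called as lists.

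In all, 132 genes differed between Th1 and Th17, 22 higher in Th1 and 110 lower, from 2 arrays a side. The count was 71 without Th17 replicate 1, 83 without Th17 replicate 2, and 37 when the 2 groups were fitted alone.

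The difference between type 1 and type 3 cells was compared between innate and adaptive cells, and the correlation was weak. Over 15536 genes the log2 differences of ILC1 from ILC3 and of Th1 from Th17, which share no array, correlated across genes at Pearson 0.135 and Spearman 0.0967, with 53.0% of genes of the same sign. The jackknife error of the Pearson value, from leaving out each array in turn, was 0.0954. Over the 906 genes called between ILC1 and ILC3 the Pearson correlation was 0.234, with 59.4% of the same sign. Over the 132 called between Th1 and Th17 it was 0.276, with Spearman 0.135 and 50% of the same sign. Without Th17 replicate 1 the correlation over every gene was 0.0668. Of 26 genes called in both, 4 were higher in both type 1 groups (CXCR3, GZMK, CCL5 and BUB1) against 0.585 for independent lists, 11 were lower in both against 3.49, and 11 went opposite ways against 3.62. Of those 4, each lost its Th1 call without 1 or more of the helper T arrays (adjusted p up to 0.567 for CCL5, without Th17 replicate 1, and 0.425 for BUB1, without Th1 replicate 2). Among those lower in both were BANK1 and CCR6, and among the opposite ones was MS4A1. CCR6 is a sort marker of ILC3 and Th17, and CXCR3 of Th1 alone. BANK1 and MS4A1 are B cell markers, which were high in both Th17 arrays. The sort and the B cell transcripts therefore enter these counts. The shared fit also gives a gene the same variance in both contrasts, so genes of small spread are called more readily in both. The numbers for independent lists are therefore no chance level, in the same or in opposite directions.

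**Figure D4:**
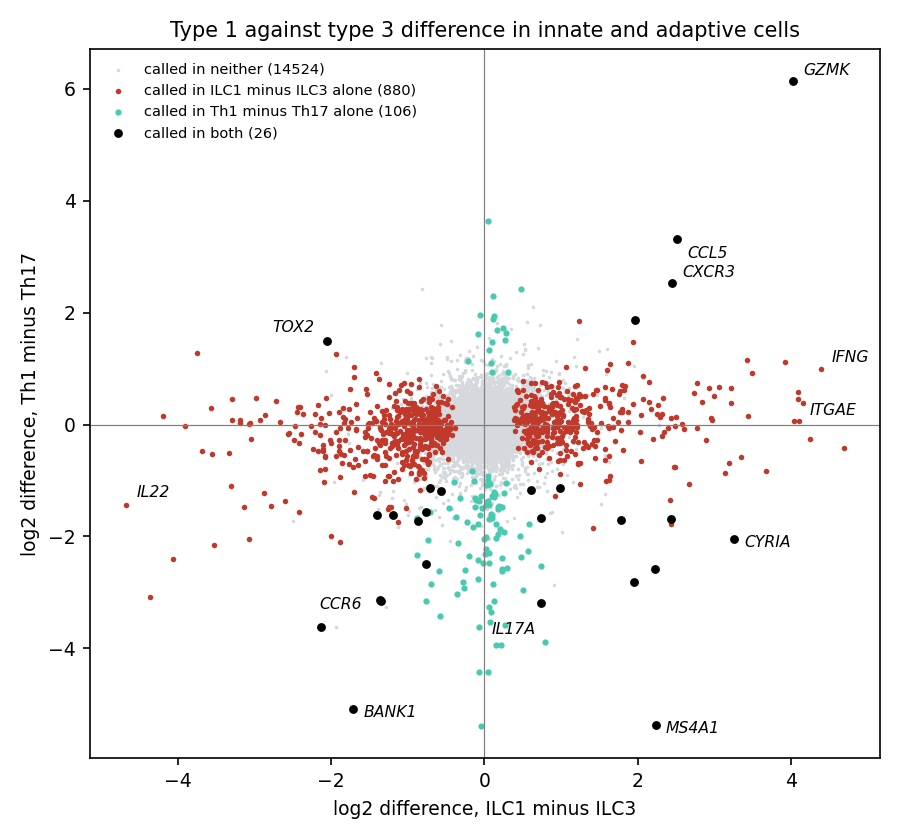
Log2 difference of ILC1 from ILC3 (horizontal) against that of Th1 from Th17 (vertical) for 15536 genes; each point is a gene, coloured by the comparison in which it was called. Of the called genes, 880 were called between ILC1 and ILC3 alone, 106 between Th1 and Th17 alone and 26 in both. A gene called in a single comparison may also differ in the other. The comparison of Th1 with Th17, with 2 arrays a group, recovered 56% of simulated log2 changes of 1.

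Whether the innate difference itself departs from the adaptive one was tested as an interaction, positive where ILC1 less ILC3 exceeds Th1 less Th17. CD160 (5.11 ± 0.51), IKZF3 (3.64) and ZEB2 (4.12) had a higher innate difference, as had ITGAE (4.05 ± 0.36) through the sort of ILC1, and ELAPOR1 (-5.02 ± 0.80), GNAI1 (-3.86 ± 0.59) and ABCB5 (-3.74 ± 0.53) a lower one. IL17A had an interaction of 3.55 ± 0.41, since it differed between the helper T groups alone, and IL22 was not called (-3.23 ± 1.29, adjusted p = 0.381), though it was without Th17 replicate 2 (-5.31, adjusted p = 0.0391). B cell markers led the interaction with 13 of 14 genes above zero over all genes and adjusted over the list alone, with MS4A1 at 7.60, CD22 at 5.33 and CR2 at 4.47 (adjusted p = 9.50e-44, and adjusted p = 1.30e-06 with an estimated correlation).

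The type 1 (2 of 18 higher, 9 adjusted over the list alone), cytotoxic (4 of 16, 7 adjusted over the list alone), NK receptor (4 of 17, 8 adjusted over the list alone) and class II lists (4 of 8, 5 adjusted over the list alone) were higher, with CD244 at 3.24 and HLA-DMB at 4.16. No class II gene was called between ILC1 and ILC3, and 4 of 8 were lower in Th1 than in Th17, where the B cell markers were lower as well. Also higher were the innate transcription factors (2 of 12, 5 with 1 lower adjusted over the list alone) and residency genes (0 of 13, 6 with 1 lower adjusted over the list alone). The follicular helper list was lower (2 of 13 lower and 1 higher, 3 and 2 adjusted over the list alone), with TOX2 at -3.55. Each of these 7 had an adjusted p of at most 0.00408, and of at most 0.0439 with an estimated correlation. The type 3 list (3 higher and 3 lower of 21, 3 and 5 adjusted over the list alone) gave adjusted p = 0.00408, and adjusted p = 0.487 with an estimated correlation, and lost its call without Th1 replicate 2 or Th17 replicate 1 (adjusted p up to 0.0994).

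In all, 253 genes were called in the interaction, 172 above zero and 81 below. The count was 155 without Th1 replicate 1, 135 without Th17 replicate 1 and 136 without Th17 replicate 2, and 206 when genes that follow the B cell markers were left out, a check chosen after the data were seen.

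The remaining marker and background lists were not called by camera in the 8 comparisons. No member of the 7 erythrocyte and platelet markers was called, and of 10 epithelial markers only EPCAM was, higher in ILC3 than in NK cells (1.10, adjusted p = 0.0123, and 2.54 with the median of its probe sets). Of 8 stromal and endothelial markers PECAM1, which leukocytes also express, was the one called. It was higher in innate than in helper T cells (4.57, and 2.65 with the median of its probe sets) and in ILC3 than in NK cells (1.89). Of 2 CD8 genes, CD8A was lower in ILC1 (-2.84) and in ILC3 (-3.48) than in NK cells, and fry gave adjusted p of 0.00547 and 0.000375 for this list. GZMB was the only called member of the 5 plasmacytoid dendritic cell markers. Plasma cell markers had at most 2 of 6 members called in a comparison. The lowest adjusted p of camera for these lists was 0.114, and glycolysis (lowest 0.110), interferon-stimulated (0.221) and cytokine receptor genes (0.184) passed in none. Fry also passed the stromal list in 3 comparisons and the plasmacytoid list in 1 (adjusted p from 0.000388 to 0.0185). OAS3 was lower in ILC1 than in ILC3 (-0.63), and PKM was higher (0.54). Of the 72 list calls made with camera's preset correlation over the 25 lists and 8 comparisons, 43 held with an estimated correlation. Camera asks whether a list differs more than other genes, while fry, which passed 77, asks whether its members move one way on balance.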

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

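Among the tests here, the second B cell list, the mixing test for ILC1 replicate 1 and the splits of the arrays were set out before their results were seen, and the others were chosen only after. B cell markers were higher in both Th17 arrays than in both Th1 arrays by a median of 2.79 on the log2 scale, and the mean levels in Th17 were 9.71 for MS4A1, 9.15 for CD79A and 8.98 for CD22. B cells in the preparation are a candidate source, which the CD4 gate should remove: a second list of B cell genes, of which 14 of 16 were measured, had a median difference of 2.2957, with 11 called. None of the 14 markers of the first list is in another list, and 8 of them lay above the 30th percentile in both Th1 arrays. Other cells in place of helper T cells are argued against for the cell types of 6 other marker lists, the largest median of which was 0.1566. A lower share of helper T cells through B cells alone would leave those lists unchanged, so they cannot decide on it. The plasma cell list, left out of the 6 as of the B lineage, had 0.245. Helper T cells that express B cell genes themselves cannot be told apart from B cells, as the T cell receptor list differed by a median of -0.0398 and a small share of B cells would leave it as it is.

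ILC1 replicate 1 had IL22 at 7.21, IL23R at 8.84 and KIT at 10.16, above the other ILC1 arrays. ILC3 cells mixed into that preparation are a candidate source, which the test leaves open: 26 genes high in ILC3 put the share at a median of 25.8% (quartiles 16.4% and 36.8%), and 242 genes high in ILC1 shifted by -0.2532. The formula set out beforehand, the log2 of 1 less the share, needs -0.430, with -0.215 as the bound against mixing. Counting what ILC3 cells themselves express of those genes, a change made to that formula, the need is -0.2603. The same measure was -0.0787, -0.161 and 0.0752 in ILC1 replicates 2, 3 and 4, of which replicate 3 had no excess of ILC3 genes (-0.0149), so the margin is narrow. A preparation or donor shared with ILC3 replicate 1 may add to it, as their residuals over 14630 uncalled genes correlated at 0.3086, above the 19 other pairs (-0.194 to 0.155). A swapped label is argued against, since ITGAE was 8.4892 there and at most 5.08 in ILC3. A biological difference between the cells sorted for this array stays open and was not tested.

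Immediate early genes were higher in ILC1 and ILC3 of tonsil than in blood NK cells, though for ILC3 the list had adjusted p = 0.168 with an estimated correlation. Within tonsil the median innate less adaptive difference was -0.0645, so these genes were not raised in innate cells as a class. NK cells are innate as well, so innate identity was an unlikely cause beforehand. That value therefore lends nothing to the causes that follow. Handling of tonsil tissue before the sort could raise them, and helper T cells also exceeded NK cells, by a median of 0.934 with 11 of 18 members called. Activation of the cells within the tonsil could as well, with a median ILC1 less NK difference of 1.8775 over 5 activation genes. These 2 cannot be told apart, since every tonsil sample shares the tissue and its handling.

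For the counts of called genes, other divisions of the arrays were run in 4 comparisons. In each, only the real split, of those run, gave as many genes. Every other split mixes differently sorted cells, so this outcome was likely beforehand. It bears on a random division of the arrays alone and not on tissue, donor or kit. ILC1 less ILC3 had 906 against at most 220 in the others (100 of 126 possible splits run), ILC1 less NK 1379 against 4 (35 of 35), and ILC3 less NK 2837 against 1252 (100 of 126). Innate against helper T cells, fitted as 2 groups of the 13 tonsil arrays, had 1437 against 1 (100 of 715).

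Of 528 groups of arrays examined for genes and lists in the text, 26 had an array far from its fellows by Dixon's criterion. Chance flags about 1 in 20 groups, which is 26.4 here. Most flags fell on ILC1 replicate 3 and NK replicate 4. The total near the chance number therefore does not exclude that these arrays depart as a whole. In ILC1 replicate 3 these were CCL3 (8.19), CX3CR1 (4.68), HLA-DPB1 (7.30), LYZ (7.16), S100A8 (5.37), TNIP3 (4.63) and the means of the B cell (4.94) and CD8 T cell markers (6.50). In the other ILC1 arrays they were KLF3 (5.31), ZNF667-AS1 (7.66) and the ribosomal protein mean (11.33) in replicate 2, and CD28 (3.19) and the tissue residency mean (8.59) in replicate 4. In ILC3 they were GNLY (9.41) and SH2D1B (9.24) in replicate 5 and the plasma cell mean (6.97) in replicate 4. In NK replicate 4 they were CD22 (5.99), CTSW (11.10), GZMA (11.88), IL23R (3.51), NKG7 (12.86), THEMIS (4.57) and the means of the type 3 (5.59) and glycolysis lists (7.78). HLA-DPA1 (9.63) in NK replicate 1 and IL21 (2.85) in NK replicate 3 complete them. The mean of the monocyte list, which holds LYZ and S100A8, was not flagged. It was 5.06 in ILC1 replicate 3 and 4.34 to 4.57 in the other ILC1 arrays.

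The type 1 less type 3 difference departed between innate and adaptive cells at 253 genes by the interaction test. By gene the interaction was 7.60 for MS4A1, 5.33 for CD22, 5.30 for CYRIA, 5.11 for CD160, -5.02 for ELAPOR1, -3.89 for SPINK2, -3.86 for GNAI1 and -3.74 for ABCB5. The SPINK2 call was lost without Th1 replicate 2 (-3.57, adjusted p = 0.0625) or Th17 replicate 2 (-3.60, 0.0757). By list the median was 1 for the type 1 program, 1.12 for cytotoxic, 0.89 for NK receptor, -0.88 for follicular helper, 0.75 for innate transcription factor, 1.04 for residency, 1.27 for class II and 2.84 for B cell genes.

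Probe sets outside the gene table also differed. Among those bright enough to test, 8094 had no gene listed and 1455 had several symbols. Of the 8094, 49 were called between ILC1 and ILC3 and 178 between innate and helper T cells. Of the 1455, the numbers were 44 and 152.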

How the results depend on the processing

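Leaving out pairs of NK arrays, the Th17 arrays or genes that follow the B cell markers was chosen after the data were seen. Of 482 called results of named genes, 355 stayed called under every alternative, and of 72 list calls 43 did, with no change of direction in either. Over single arrays left out, the counts ran from 688 to 1048 for ILC1 less ILC3, 922 to 1386 for ILC1 less NK, 2242 to 2927 for ILC3 less NK, 1557 to 2119 for innate less adaptive, 668 to 1029 for ILC1 less Th1, 718 to 1343 for ILC3 less Th17, 71 to 136 for Th1 less Th17 and 135 to 289 for the interaction. The shared calls ran from 319 to 499, the correlation of the axes from 0.0668 to 0.170, list calls from 67 to 74 and called named genes from 420 to 467. The lowest counts with helper T cells came without an array of a group of 2, whose lone array is then assumed to vary like the other groups. A 2-fold minimum left 438, 596, 1116, 771 and 809 genes in ILC1 less ILC3, ILC1 less NK, ILC3 less NK, innate less adaptive and ILC3 less Th17, by its construction. Fits of only the groups compared, with fewer arrays, gave 604 genes in ILC1 less Th1 and 37 in Th1 less Th17. Without NK replicates 3 and 4, ILC1 less NK gave 733 and ILC3 less NK 1830, and without NK replicates 1 and 2, 763 and 1819, with fewer arrays each time. Without Th17 arrays innate less adaptive gave 1473, and without 36 genes that follow the B cell markers (correlation above 0.9) ILC3 less Th17 gave 1244, Th1 less Th17 89 and the interaction 206. At least 21 of the 36 are in neither list of B cell genes, while 21 list members were higher in Th17 than in each other group. Some B cell genes, which follow less closely, therefore stay in the last 3 counts. The difference in array similarity was 0.0534 over every gene, the correlation of the axes 0.234 over called genes alone, and 43 list calls held with an estimated correlation. For those 3 the cause was not tested.

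The labels give no pairing by replicate number, and 1 of 4 ILC1 arrays correlated best in its residuals with the ILC3 array of its number. Same-numbered Th1 and Th17 arrays correlated at 0.373, a single value for both numbers with 2 arrays a group, which leaves pairing there open. With replicate number as a replicate block the counts were 847, 1330, 2703, 1846, 954, 1187, 124 and 232 in the order above, with 450 shared calls. Signal over background limits the 9 list members and 2858 genes too dim to test. It also limits tested genes with a group mean below the filter level of 3.95 to 4.07. Their differences from that group may be minimums. Examples are CX3CR1 in ILC1 (mean 3.59), IL23R in NK cells (2.97) and CXCL13 in ILC1 (3.08).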

Other observations

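The comparisons below were all chosen after the data were seen, and so were the genes named here, chosen after their values were seen. Each population had transcripts higher than in every other one. By limma's adjusted p in each of the 4 contrasts of a group, 37 genes were higher in ILC1 than in each other group. The numbers were 203 in ILC3, 314 in NK cells, 17 in Th1 and 64 in Th17 cells. For 33, 177, 281, 17 and 64 of them, every array of the group lay above every other array. In 20 simulations without group differences no group had such genes. With no gene changed the adjusted p is far stricter than in these data. The simulations therefore give no share of false genes among these numbers. Beside ITGAE, ILC1 stood out by SPRY2, an inhibitor of receptor tyrosine kinase signalling, by at least 2.94 on the log2 scale over each other group, the tetraspanin CD9 (2.58), ADGRG3 (2.40) and the chemokine receptor CCR1 (2.13). ILC3 stood out by the lysophosphatidic acid receptor LPAR1 (3.29), FGD6 (3.19) and LST1 (3.18).

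NK cells stood out by DAB2 (at least 3.48) and FCRL6 (3.08), and these differences also hold the contrast of blood with tonsil. Th1 cells stood out by the thyrotropin receptor TSHR (2.29), GNG4 (1.88), the growth factor receptor FGFR2 (1.73) and the transcription factor FOXB1 (1.61). Of the 64 genes of Th17 cells, 21 were in 1 of the 2 lists of B cell genes and 21 others followed the B cell markers across arrays (correlation above 0.9), so the count also holds the B cell transcripts of both Th17 arrays. Beside IL17A, they included the B cell genes CD180 (3.32) and TCL1A (3.26), IL6 (3.37) and CYBB (3.33), a subunit of the phagocyte oxidase that B cells also express.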
